A study of Caenorhabditis elegans with 12 samples.

How the data were processed

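RNA was sequenced from whole C. elegans animals at the fourth larval stage (L4) in 4 strains, with 3 biological replicates per strain according to the series design. The strains were the wild type, the mbl-1 mutant carrying the allele tm1563, and 2 strains edited to make a single MBL-1 protein isoform, 1 for the short form and 1 for the long form. The deposited tables code the edited strains as SH and ME. Which of the alleles syb4318 and syb4345 each code stands for was not given in the sources used here, so the codes are used throughout. Per the labels' protocols, animals were synchronised by bleaching, grown at 20 C on OP50 bacteria until L4 and extracted with TRIzol, and poly(A) RNA was made into libraries for 150-base paired reads on a NovaSeq instrument. The strand handling of the read counting was not stated, so reads of a gene and of an overlapping or antisense gene could not be told apart.

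The authors deposited read counts per gene as whole numbers, in 3 tables that each hold 1 mutant strain and the wild type. Reads were aligned with HISAT2 to the WBcel235 genome, per the submitters' processing notes, and DESeq2 is named there as well, with no version for any of them. Each table also gives the authors' log2 fold changes and the authors' p-values with their adjusted form, and a further deposited table gives FPKM for 46638 genes. The authors also deposited lists of differential splicing events per mutant strain, which give inclusion levels, junction reads, p-values and false discovery rates. The splicing caller and its settings were not given in the sources used here. The splicing lists hold called events alone, so the number of events tested per type was recovered from the relation between each p-value and its adjusted value.

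The wild-type counts differed in 0 cells between the 3 tables. The tables held 22105 genes in all, of which 19812 were in all 3 and were used, and 2293 were left out. The 11730 counts missing for those genes were recovered from FPKM, and the largest was 1 read. For 100.0% of genes in the library with the lowest share, FPKM gave the deposited count within 0.1 reads. The 36 per-library columns of normalized counts and repeated FPKM in the count tables were not used. Gene names came from the Ensembl annotation for 18512 genes and from the RefSeq table for 935, and 365 genes kept their identifier. Coordinates are those of the authors' files (WBcel235), 1-based. Of the genes used, 17500 were protein-coding.

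Counts were tested with edgeR 4.0.16, using TMM scaling, the filterByExpr filter (minimum count 10, minimum total 15) and the robust quasi-likelihood F test, in 1 fit of all 12 libraries with strain as the only factor. The fit covered 15191 genes and 6 comparisons. Adjusted p-values are Benjamini-Hochberg values over those 15191 genes per comparison, and 0.05 was the threshold. Fold changes are log2 values from that fit, errors after ± are standard errors for fold changes and SDs for CPM, and log2 CPM used a prior count of 2. All adjusted p-values of single genes in the text are edgeR quasi-likelihood values unless another tool is named. Total counts ran from 28186206 to 35189354 per library. Chi-square statistics per gene between replicates of 1 strain ran from 5.77 to 45.0, above counting noise in every pair, so no library was a copy of another. Intervals given for ratios of low counts are exact binomial intervals and cover counting error only.

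Before the data were examined, 33 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The lists were body wall muscle, pharyngeal muscle, pan-neuronal genes, acetylcholine and GABA transmission, touch receptor neurons, tubulins, FMRFamide-like neuropeptides, neuropeptide-like proteins, splicing regulators, col collagens, named cuticle genes, the molting cycle, vitellogenins, major sperm proteins, other sperm genes, oocyte and eggshell genes, germline genes, zygotic embryo genes, gut proteases and intestinal fate genes, heat shock genes, the unfolded protein response, pathogen response genes, pals genes, cytochrome P450 genes, glutathione transferases with UDP-glucuronosyltransferases, DAF-16 targets, fatty acid genes, nuclear oxidative phosphorylation genes, the mitochondrial genome, ribosomal proteins, histones, dosage compensation and sex determination genes, and reference genes. Lists were tested with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over all 198 list tests. Camera with an estimated correlation and fry were run beside it. With an estimated correlation no list passed 0.05 in any of the 6 comparisons, and that value is given beside each call. List members that rose or fell are counted over all genes tested and also adjusted over the list alone.

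Genes were named by rule. The rule took mbl-1 first, then per comparison the 10 largest rises and the 10 largest falls among genes past the threshold whose replicates did not overlap and whose mean FPKM was 1 or more. It also took up to 4 called members of each list (2 members of high expression where none was called), 5 genes per direction called in all 3 mutants, and the splicing events with the largest inclusion differences whose replicates did not overlap. A subset is printed, led by those whose call held when any 1 library was left out. Genes or events outside the rule are said to be chosen after their values were seen. Families of near-identical copies (histones, major sperm proteins, hsp-16 genes, nsp genes) share reads, and values of single members are uncertain.

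The 3 comparisons with the wild type share its libraries. Unchanged groups were therefore simulated against those libraries in 20 rounds, and simulated correlations, covariances and overlaps are given beside the observed ones. Same-numbered replicates were checked for pairing through the correlation of their deviations from strain means. For wild type and tm1563 these were 0.20, 0.26 and 0.39, and for tm1563 and SH 0.17, 0.25 and 0.56, so those pairs of strains met the criterion of over 0.1 in each pair, as a hint from the data that the labels do not state. The other 4 pairs of strains did not.

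Spliced and changed genes were compared with Fisher's exact test (two-sided). For a background matched on expression, as many genes were drawn at random from the same strata of expression, with odds ratios pooled over strata. Analyses were tested on simulated data with known changes. In simulated counts for tm1563 against the wild type over 15191 genes, 58.2% of genes changed 1.5-fold were recovered, 79.1% of those changed 2-fold and 97.0% of those changed 4-fold, with 6 false calls among 162. The changed genes were drawn only from genes with higher mean counts, and each library was drawn independently. Recovery of genes with few reads, and false calls where replicates deviate together, were thus not measured. A further 40 simulations over 15000 genes made being spliced and being changed both depend on expression level, with no other link between them. There the unmatched overlap test called 38 and the matched test 3. Alternatives were other filters, thresholds, pseudocounts on FPKM (limma), DESeq2 1.42.0 and its size factors, the 6 libraries of each comparison alone, the replicate number as a block, and each library left out in turn. Settings added after the data were seen were replicates 1 and 2 alone, an FPKM filter of 1, and a covariate for the axis along which replicates of 1 strain differ. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.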

Results

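Gene expression and splicing were measured by RNA-seq in whole C. elegans animals at the L4 stage. The 4 strains had 3 biological replicates each, 12 libraries in all. They were the wild type, the mbl-1 mutant tm1563, and the SH and ME strains, each edited to make a single isoform of MBL-1. MBL-1 is the worm member of the muscleblind family of RNA-binding proteins, which regulate alternative splicing in muscle and neurons. Total counts were 32639694, 33779555 and 35189354 in wild-type replicates 1 to 3, and 32135194, 33704978 and 28212459 in tm1563. They were 29993499, 33106047 and 28186206 in SH, and 31407372, 30895075 and 31897067 in ME. The 10 most abundant genes took between 5.52% and 6.41% of the counts of a library.

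The edited locus was examined first, to see what each strain made from mbl-1 (K02H8.1, X:17001728 to 17008361, WBcel235). The 225-base coding cassette exon at X:17006973 to 17007197 separated the strains. According to the authors' deposited tables its inclusion was 0.535, 0.513 and 0.588 in the wild type and 0.047, 0.031 and 0.044 in SH, a difference of -0.505 with a false discovery rate of 5.98e-280. In ME it was 1.0 in each of the 3 replicates in the authors' deposited tables, a difference of 0.455 with a false discovery rate of 2.91e-118. In tm1563 the authors' deposited tables gave 0.716, 0.688 and 0.713, a difference of 0.16 with a false discovery rate of 1.35e-13. Total mbl-1 RNA was 63 ± 1.2 CPM in the wild type (SD, n = 3), 55.4 ± 6.44 in tm1563, 56.1 ± 4.94 in SH and 52.8 ± 6.29 in ME. All 9 mutant libraries lay below all 3 wild-type libraries, but no difference passed the test, with log2 fold changes of -0.18 (adjusted p = 0.248), -0.17 (adjusted p = 0.257) and -0.26 (adjusted p = 0.069). The extent of the tm1563 deletion was not given in the sources used here, so the total count does not check that label.

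**Figure D1:**
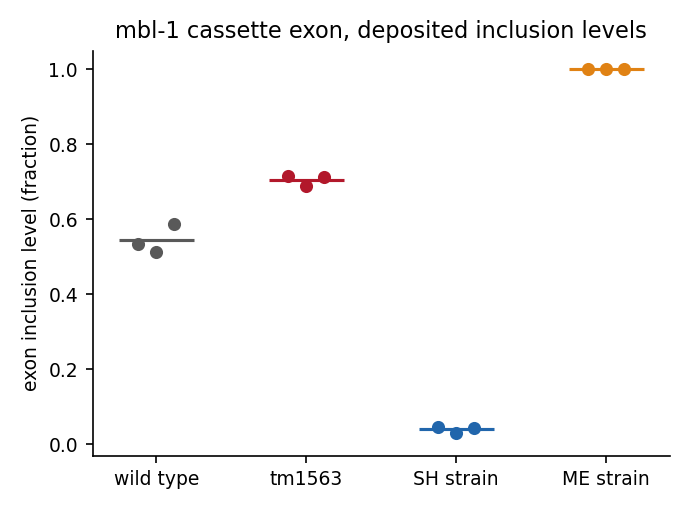
Inclusion of the mbl-1 cassette exon at X:17006973 to 17007197 in each library, from 0 (skipped) to 1 (included), by strain, as given in the authors' deposited tables. The SH libraries lay between 0.031 and 0.047, the ME libraries at 1.0, and the wild-type libraries between 0.513 and 0.588.

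The first 2 principal components of log2 CPM held 38% and 29% of the variance. The ME libraries were set apart on the second component, at -60.4, -51.4 and -33.3. On the first component replicate 3 lay apart from replicates 1 and 2 in 3 strains: wild type at 22 against -29.2 and -31, tm1563 at 4.4 against -54.2 and -52.1, and SH at 64.3 against 44 and 35.9. The deviations of replicates from their strain means followed 1 main axis that held 39.1% of the within-strain variance. Along it, the median loading of oocyte genes was at percentile 97.6 of the genes, germline genes at 94.7 and sperm genes at 92.3, while vitellogenins were at 5.4, touch receptor genes at 13.8 and pharyngeal muscle genes at 14.5. Scores on this axis were -30.5, -34.1 and 14.6 in the wild type, -48.2, -46.7 and 22.4 in tm1563, 26, 21.3 and 55 in SH, and 9.1, 5.9 and 5 in ME.

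**Figure D2:**
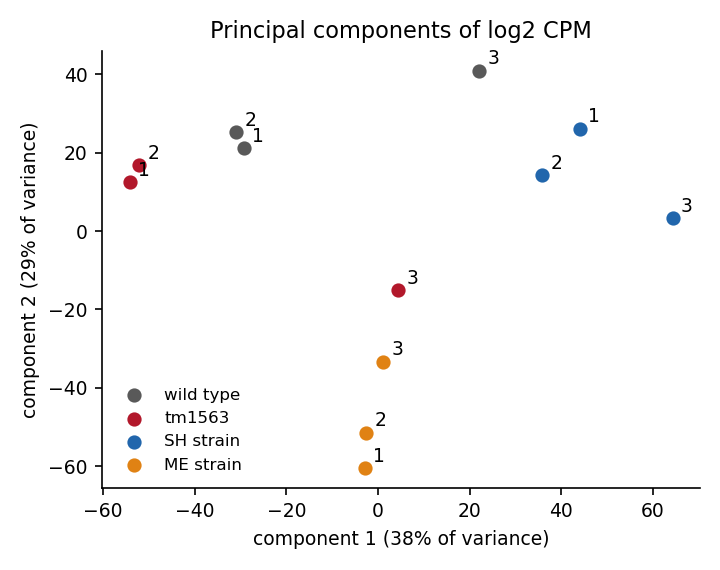
First and second principal components of log2 CPM for the 12 libraries, coloured by strain, with the replicate number beside each point. The components hold 38% and 29% of the variance, and replicate 3 of the wild type, tm1563 and SH lies to the right of replicates 1 and 2 of its strain.

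The comparison of tm1563 with the wild type asked which transcripts differ in the mbl-1 mutant. Several genes of the touch receptor neurons fell. The beta-tubulin gene mec-7 fell from 122 ± 10.5 to 22.3 ± 2.08 CPM (SD, n = 3), a log2 change of -2.46 ± 0.09 (adjusted p = 3.58e-08). The alpha-tubulin gene mec-12 changed by -1.82 ± 0.09 (adjusted p = 2.20e-07) and mec-17, which encodes an alpha-tubulin acetyltransferase, by -1.56 ± 0.07 (adjusted p = 2.20e-07). Body wall muscle, named cuticle, molting, histone and heat shock genes moved up as lists. The col collagens, the vitellogenins (3 of 6 called) and many detoxification genes moved down. In total 2488 of 15191 genes changed, 1431 up and 1057 down, and 385 of those that rose and 108 of those that fell did so by a log2 change of 1 or more. The authors' deposited table gave 2470 genes for the same comparison.

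Of the 16 touch receptor genes tested, 5 fell and 1 rose in tm1563 (5 and 2 adjusted over the list alone), with a median of -0.20 and a camera adjusted p of 4.51e-12, against adjusted p = 0.254 with an estimated correlation. Besides mec-7, mec-12 and mec-17, these were mec-18 (-0.93 ± 0.10, adjusted p = 9.94e-05) and mec-9 (-0.53 ± 0.12, adjusted p = 0.0117). The 1 that rose was unc-86, a POU factor of these neurons (0.50 ± 0.15, adjusted p = 0.0439). The homeodomain factor mec-3, which activates touch receptor genes, had a log2 change of -0.28 ± 0.22 (adjusted p = 0.444). In this list mec-9, unc-86 and mec-3 were named after their values were seen. Among 14 tubulins, which include mec-7 and mec-12, 3 fell and 1 rose, as they did adjusted over the list alone, with a median of -0.14 (camera adjusted p = 1.02e-10, and adjusted p = 0.212 with an estimated correlation). The beta-tubulin ben-1 fell by 1.26 on the log2 scale (adjusted p = 1.43e-06) and tbb-6 rose by 1.12 ± 0.17 (adjusted p = 0.00117). Other neuronal lists did not pass camera: pan-neuronal genes had a median of 0.03 (6 of 36 rose and 3 fell, camera adjusted p = 0.906), acetylcholine and GABA genes 0.12 (2 of 29 rose and 1 fell, 0.497), FMRFamide-like peptides 0.10 (5 of 30 rose and 1 fell, 0.329) and neuropeptide-like proteins -0.02 (3 of 56 rose and 7 fell, 0.364). Adjusted over the list alone these lists had 6, 2, 5 and 3 members up and 4, 0, 1 and 7 down. By fry the acetylcholine and GABA genes passed upward (adjusted p = 0.00788). The kinesin gene unc-104 fell by 0.56 on the log2 scale (adjusted p = 0.000654) and unc-13, needed for vesicle priming, rose by 0.52 ± 0.10.

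**Figure D3:**
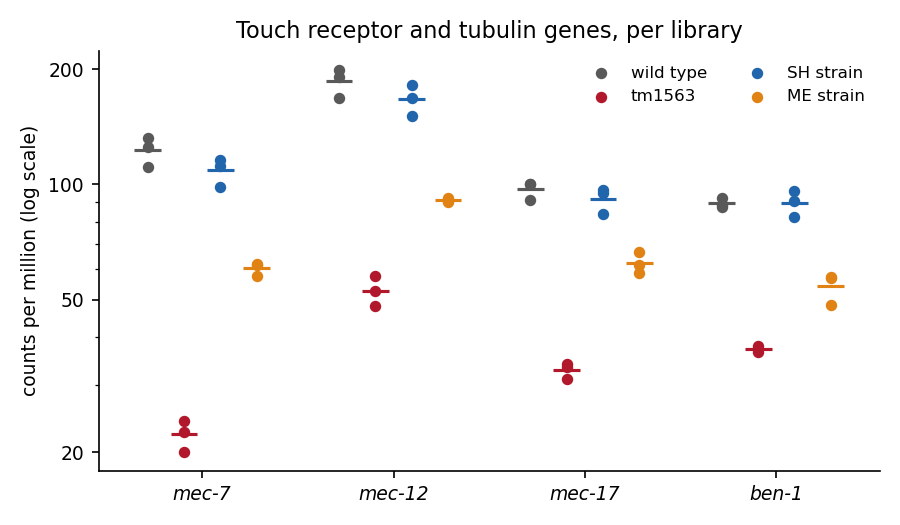
CPM (log axis) of mec-7, mec-12, mec-17 and ben-1 in each library, by strain, with a line at each strain mean. For mec-7 the tm1563 libraries lie between 20.1 and 24.2 CPM, the ME libraries between 57.6 and 61.9, and the wild-type libraries between 111 and 132.

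Body wall muscle genes moved up in tm1563, with 12 of 34 higher and 0 lower (14 and 0 adjusted over the list alone). The camera adjusted p was 4.99e-08, and adjusted p = 0.435 with an estimated correlation. The titin-like gene ttn-1 rose by 1.15 ± 0.11 (adjusted p = 5.10e-05), unc-22, which encodes twitchin and was chosen after its value was seen, by 0.77 (adjusted p = 0.000805), deb-1, which encodes vinculin, by 0.53 ± 0.05 (adjusted p = 4.24e-05) and the myosin gene unc-54 by 0.70 ± 0.10 (adjusted p = 0.000647). Of 8 pharyngeal muscle genes, 1 rose (0 adjusted over the list alone, camera adjusted p = 0.906). With replicates 1 and 2 alone the median of this list turned from -0.20 to 1.13. Named cuticle genes rose in 14 of 26 cases and fell in 1 (18 and 1 adjusted over the list alone), with a median of 0.59. This list's camera adjusted p was 1.10e-10, and adjusted p = 0.382 with an estimated correlation. The apical matrix gene noah-1 went from 25.7 to 105 CPM (2.03 ± 0.24, adjusted p = 0.000663). Molting genes followed, with 14 of 25 up and 2 down (16 and 2 adjusted over the list alone), and a median of 0.65. By camera the adjusted p was 6.88e-09, and adjusted p = 0.310 with an estimated correlation, led by mlt-11, which encodes a protease inhibitor (1.89 ± 0.18, adjusted p = 0.000148). With replicates 1 and 2 alone the medians were 0.39 for named cuticle and 0.40 for molting genes. The col collagens went the other way, with 16 of 121 down and 8 up (27 and 11 adjusted over the list alone), and a median of -0.36. In the camera test the adjusted p was 5.65e-05, and adjusted p = 0.602 with an estimated correlation.

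Histone genes rose in 19 of 28 cases in tm1563 and fell in 0 (20 and 0 adjusted over the list alone), with a median of 1.79. Tested with camera, the list had an adjusted p of 1.45e-18, and adjusted p = 0.254 with an estimated correlation. Heat shock genes rose in 8 of 14 cases and fell in 0 (10 and 0 adjusted over the list alone), with a median of 0.48. For this list the camera adjusted p was 2.15e-10, and adjusted p = 0.254 with an estimated correlation. The chaperone gene hsp-70 went from 4.81 to 18.1 CPM (1.91 ± 0.15, adjusted p = 1.77e-05) and hsp-16.2 from 0.924 to 7.30 CPM (2.97 ± 0.21, adjusted p = 7.20e-06). The 6 vitellogenins, which encode yolk proteins, had a median of -1.70, with 3 lower (6 adjusted over the list alone), and -1.15 with 0 called with replicates 1 and 2 alone. Camera returned an adjusted p of 2.01e-05, and adjusted p = 0.429 with an estimated correlation. Glutathione and UDP-glucuronosyl transferases fell in 27 of 94 cases and rose in 3 (30 and 4 adjusted over the list alone). The camera adjusted p was 1.36e-06, and adjusted p = 0.382 with an estimated correlation. An example was ugt-53 at -1.21 ± 0.15 (adjusted p = 0.000371). Gut protease and intestinal fate genes rose in 7 of 19 cases (7 adjusted over the list alone). This list's camera adjusted p was 0.000618, and adjusted p = 0.553 with an estimated correlation. The cathepsin B-like gene cpr-1 rose from 103 to 369 CPM (1.84 ± 0.18, adjusted p = 0.000175). Ribosomal protein genes (median -0.07, 2 of 77 down, camera adjusted p = 0.00904, and adjusted p = 0.843 with an estimated correlation) and pals genes (median 0.40, 4 of 25 up and 1 down, camera adjusted p = 0.0272, and adjusted p = 0.486 with an estimated correlation) passed with less margin. With p-values adjusted over the list alone, 0 ribosomal protein genes were called, and 4 pals genes rose and 1 fell. Leaving out tm1563 replicate 2 gave camera adjusted p-values of 0.0767 for ribosomal proteins and 0.0546 for pals genes, and leaving out wild-type replicate 3 gave 0.0876 and 0.0528.

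The remaining lists did not pass camera in this comparison. By fry dosage compensation and sex determination genes (adjusted p = 0.00174) and splicing regulators (0.0471) passed upward, and zygotic embryo genes (0.0401) and cytochrome P450 genes (0.0462) downward. Splicing regulators had a median of 0.05 (8 of 42 rose, 1 fell), DAF-16 targets 0.00 (3 of 24 rose, 5 fell), pathogen response genes -0.04 (5 of 33 rose, 8 fell) and the unfolded protein response -0.04 (3 of 23 rose, 5 fell). Germline genes had a median of 0.37 (3 of 30 rose, 1 fell), the mitochondrial genome -0.18 (1 of 12 fell) and dosage compensation and sex determination genes 0.18 (1 of 17 each way). Medians were 0.52 for 23 oocyte genes, -0.04 for 26 sperm genes, -0.24 for 2 zygotic embryo genes, -0.06 for 41 nuclear oxidative phosphorylation genes and 0.03 for 8 reference genes. In these 5 lists edgeR called 0 genes, an unadjusted p was under 0.05 for 1, 1, 0, 0 and 2 genes, and DESeq2 called 0, 0, 0, 1 and 1. Cytochrome P450 genes had a median of -0.12 (5 of 65 rose, 12 fell, camera adjusted p = 0.0572, 0.0444 with the replicate number as a block). Fatty acid genes had a median of -0.16 (7 of 48 rose, 8 fell, camera adjusted p = 0.0639, 0.0380 with the block), and major sperm proteins -0.24 (0 of 31 called by edgeR or DESeq2 and 0 with an unadjusted p under 0.05, camera adjusted p = 0.109, 0.0204 with the block). With an estimated correlation and no block these 3 lists had camera adjusted p = 0.553, 0.774 and 0.906. Within the first of these lists cyp-29A3 fell by 1.41 on the log2 scale (adjusted p = 5.83e-05) and cyp-31A1 rose by 1.06 ± 0.08 (adjusted p = 1.13e-05).

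The largest single changes in tm1563 included a pair of saposin-like genes on X. The gene spp-21 (X:11490130) had 368 reads against 4 in the wild type, a ratio of 99.4 (95% interval 38.5 to 367), and spp-9 (X:11487788) 137 against 7, a ratio of 21.1 (9.99 to 53.6). K02H8.5, a transcript inside the mbl-1 locus at X:17002072 to 17002214 on the antisense strand, had 84 reads against 2 (ratio 45.4, interval 12.2 to 381), and its reads cannot be assigned to a strand. Among genes that fell, F42G10.1 went from 41.1 to 5.04 CPM (-3.02 ± 0.12, adjusted p = 3.58e-08), far-3, which encodes a fatty acid and retinol binding protein, from 105 ± 23.4 to 17.4 ± 0.726 CPM (-2.59 ± 0.15, adjusted p = 3.66e-06), and irg-5, an infection response gene, from 706 ± 77.6 to 115 ± 29.2 CPM (-2.61 ± 0.19, adjusted p = 2.27e-05).

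The SH strain was compared with the wild type to see what changes when the mbl-1 exon is nearly always skipped. Heat shock genes rose and genes of gut digestion, detoxification and pathogen defence fell, while germline, oocyte and sperm lists lay above the wild type. The chaperone gene hsp-70 rose from 4.81 ± 0.516 to 22.5 ± 2.15 CPM (SD, n = 3; 2.22 ± 0.16, adjusted p = 2.40e-05). The lysozyme genes lys-2 and lys-1 fell by 0.68 and 0.56 on the log2 scale (adjusted p = 0.000579 and 0.00101). Touch receptor genes had a median of -0.10 with 0 of 16 called by edgeR or DESeq2 and 0 with an unadjusted p under 0.05 (camera adjusted p = 0.327). Tubulins had a median of -0.06 with 0 of 14 called by either tool and 3 with an unadjusted p under 0.05 (camera adjusted p = 0.749). The test called 1661 genes, 633 up and 1028 down, where 5244 had an unadjusted p under 0.05, and the authors' deposited table gave 3080. By a log2 change of 1 or more 317 rose and 41 fell. Genes that rose made up 38.1% of the calls, but 55.6% with the replicate number as a block, 51.9% with DESeq2, 54.8% in the authors' deposited table and 59.5% without wild-type replicate 3.

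This count moved with single libraries. It was 176 without wild-type replicate 2, 246 without wild-type replicate 1 and 3078 without wild-type replicate 3, and it was 1074, 604 and 206 without SH replicates 1, 2 and 3. DESeq2 called 2969 genes, and with replicates 1 and 2 of each strain alone, a setting chosen after the libraries were seen, edgeR called 3547, of which 1415 were among the 1661. With the within-strain axis as a covariate 86 genes passed, 85 of them among the 1661. The SH fold changes followed that axis across genes, with a correlation of 0.71 against -0.10 for tm1563 and 0.21 for ME, and genes are not independent replicates.

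The reproductive lists, whose genes lie at the high end of that axis, had large medians in SH and few called members. Oocyte and eggshell genes had a median of 1.62 with 1 of 23 up (21 adjusted over the list alone). By camera the adjusted p was 1.31e-09, and adjusted p = 0.537 with an estimated correlation. Major sperm proteins had a median of 1.24 with 4 of 31 up (29 adjusted over the list alone). In the camera test the adjusted p was 1.19e-14, and adjusted p = 0.486 with an estimated correlation. Other sperm genes had a median of 1.06 with 4 of 26 up (9 up and 1 down adjusted over the list alone). Tested with camera, the list had an adjusted p of 4.86e-06, and adjusted p = 0.553 with an estimated correlation. Germline genes had a median of 1.2 with 0 of 30 called by edgeR (0 adjusted over the list alone, 19 with an unadjusted p under 0.05, 10 called by DESeq2). For this list the camera adjusted p was 1.25e-05, and adjusted p = 0.604 with an estimated correlation. With the axis as a covariate these medians were 0.48 for oocyte genes, 0.03 for sperm genes and 0.08 for germline genes, and with replicates 1 and 2 alone 20, 17 and 20 of their members were called. Major sperm proteins had a median of 0.35 with 0 called under the covariate, and 1.48 with 29 called with replicates 1 and 2 alone.

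Heat shock genes rose in 7 of 14 cases in SH and fell in 0 (10 and 0 adjusted over the list alone), with a median of 0.43. Camera returned an adjusted p of 7.54e-12, and adjusted p = 0.254 with an estimated correlation. The small heat shock gene hsp-16.2 rose by 2.89 ± 0.21 (adjusted p = 2.99e-05) and the hsp-70 family gene F44E5.4 by 1.8 ± 0.25 (adjusted p = 0.00322). Gut protease and intestinal fate genes fell in 10 of 19 cases (13 adjusted over the list alone), with a median of -0.33. The camera adjusted p was 1.66e-08, and adjusted p = 0.382 with an estimated correlation. Glutathione and UDP-glucuronosyl transferases fell in 23 of 94 cases and rose in 1 (34 and 3 adjusted over the list alone). This list's camera adjusted p was 4.71e-07, and adjusted p = 0.382 with an estimated correlation. The glutathione transferase gst-4 fell by 0.56 on the log2 scale (adjusted p = 0.00461) and ugt-50 by 0.65. Pathogen response genes fell in 11 of 33 cases and rose in 1 (11 and 3 adjusted over the list alone). By camera the adjusted p was 6.70e-05, and adjusted p = 0.377 with an estimated correlation, and irg-4 fell by 1.00 (adjusted p = 0.00158). The unfolded protein response fell in 9 of 23 cases (15 adjusted over the list alone), with a median of -0.21. In the camera test the adjusted p was 4.91e-06, and adjusted p = 0.486 with an estimated correlation. Fatty acid genes fell in 7 of 48 cases and rose in 2 (20 and 3 adjusted over the list alone, camera adjusted p = 4.15e-06, and adjusted p = 0.429 with an estimated correlation), with the lipase gene lipl-5 at -0.47 ± 0.08 (adjusted p = 0.00895). With the axis covariate these lists kept few calls. Called members went from 10 to 0 for gut genes (median -0.20), from 24 to 1 for the transferases (-0.12) and from 12 to 4 for pathogen response genes (-0.09). They went from 9 to 0 for the unfolded protein response (-0.13) and from 9 to 0 for fatty acid genes (-0.09), but from 7 to 4 for heat shock genes (0.48).

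Molting genes rose in 5 of 25 cases in SH (11 adjusted over the list alone), with a median of 0.42. Tested with camera, the list had an adjusted p of 5.37e-06, and adjusted p = 0.377 with an estimated correlation. The secreted Notch ligand gene osm-11 rose by 0.67 ± 0.08 (adjusted p = 0.00143). Named cuticle genes rose in 4 of 26 cases (10 adjusted over the list alone, camera adjusted p = 0.000138, and adjusted p = 0.602 with an estimated correlation), a call lost without wild-type replicate 3 (camera adjusted p = 0.0992). Further lists passed with medians of 0.18 for body wall muscle (3 of 34 up), 0.21 for col collagens (5 of 121 up), -0.24 for cytochrome P450 genes (7 of 65 down and 1 up), -0.07 for splicing regulators (2 of 42 down) and -0.23 for pals genes (5 of 25 down). Adjusted over the list alone these were 0 up, 0 up, 13 down and 3 up, 2 down and 6 down. Their camera adjusted p-values were 0.000141, 0.000637, 0.00363, 0.00676 and 0.013, and those with an estimated correlation were adjusted p = 0.602, 0.717, 0.382, 0.553 and 0.429. The axis covariate left 0, 0, 0, 1 and 0 members called in these 5 lists, 1 among molting genes and 0 among named cuticle genes. Their medians were then 0.08, 0.16, -0.13, -0.05 and -0.16, with 0.33 for molting genes and 0.32 for named cuticle genes, where it had been 0.17. The median standard error over all genes also widened, from 0.141 to 0.165. The nonsense-mediated decay gene smg-6 fell by 0.52 on the log2 scale (adjusted p = 0.0013) and pals-37 by 1.91 (adjusted p = 0.0113). Histones had a median of 0.22 (camera adjusted p = 0.0797), vitellogenins -0.41 (0.29) and the mitochondrial genome -0.04 (0.397, with the test's direction upward). Within the last, COX3 and ND1, which encode respiratory chain subunits, rose by 0.83 ± 0.08 (adjusted p = 0.000236) and 0.79 ± 0.08 (adjusted p = 0.000261).

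The largest rises in SH were at 1 locus on chromosome V. F56A4.3 (V:2453414 to 2456147) went from 0.385 ± 0.150 to 83.0 ± 7.76 CPM (SD, n = 3), a log2 change of 7.72 ± 0.15 (adjusted p = 1.73e-11). Its neighbour F56A4.9 (V:2456176 to 2458286) had 834 reads against 2, a ratio of 464 (95% interval 128 to 3840). The neighbours rose in ME as well, F56A4.3 by 7.43 ± 0.15 (adjusted p = 2.79e-11) to 67.4 ± 4.09 CPM and F56A4.9 with 639 reads against 2 (ratio 345, interval 95 to 2850). In tm1563 the log2 change of F56A4.3 was -0.33. Among genes that fell in SH, far-3 changed by -1.47 ± 0.15 (adjusted p = 0.000579) and the C-type lectin gene clec-52 from 82.4 to 32.3 CPM (-1.35 ± 0.11, adjusted p = 5.29e-05).

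The ME strain was compared with the wild type to see what changes when the mbl-1 exon is always included. It had the most calls of the 3 strains, 4758 genes with 2333 up and 2425 down, against 4348 in the authors' deposited table. By a log2 change of 1 or more 731 rose and 307 fell. Named cuticle, molting and histone genes rose strongly, while col collagens went both ways. Vitellogenins, pharyngeal muscle genes and the unfolded protein response fell. The apical matrix gene noah-1 went from 25.7 to 185 CPM (2.85 ± 0.25, adjusted p = 6.75e-05) and the collagen gene dpy-7 from 6.22 to 59.6 CPM (3.26 ± 0.31, adjusted p = 9.22e-05). Touch receptor genes fell here too, with mec-12 at -1.03, mec-7 at -1.02 and mec-17 at -0.64.

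Named cuticle genes rose in 21 of 26 cases in ME and fell in 1 (21 and 1 adjusted over the list alone), with a median of 0.95. For this list the camera adjusted p was 8.46e-17, and adjusted p = 0.337 with an estimated correlation. Molting genes rose in 19 of 25 cases and fell in 1 (21 and 2 adjusted over the list alone), with a median of 0.87. Camera returned an adjusted p of 1.8e-12, and adjusted p = 0.254 with an estimated correlation. The protease inhibitor gene mlt-11 went from 52 to 248 CPM (2.25 ± 0.19, adjusted p = 4.39e-05). The col collagens went both ways, with 26 of 121 up and 14 down (27 and 15 adjusted over the list alone), and their median was -0.26 (camera adjusted p = 0.43). Histone genes rose in 22 of 28 cases (25 adjusted over the list alone), with a median of 1.72. The camera adjusted p was 7.64e-13, and adjusted p = 0.360 with an estimated correlation. The unfolded protein response fell in 16 of 23 cases (17 adjusted over the list alone), with a median of -0.30. This list's camera adjusted p was 3.45e-07, and adjusted p = 0.429 with an estimated correlation, and calreticulin (crt-1) went from 3500 to 2500 CPM (-0.49 ± 0.07, adjusted p = 0.000549). All 6 vitellogenins fell, with a median of -2.40. By camera the adjusted p was 7.68e-06, and adjusted p = 0.411 with an estimated correlation, and vit-3 went from 657 to 125 CPM (-2.40 ± 0.44, adjusted p = 0.00311). Ribosomal proteins rose in 30 of 77 cases (41 adjusted over the list alone), with a median of 0.18. In the camera test the adjusted p was 1.51e-05, and adjusted p = 0.774 with an estimated correlation.

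Of 8 pharyngeal muscle genes, 6 fell in ME (7 adjusted over the list alone), with a median of -3.46. Tested with camera, the list had an adjusted p of 0.000392, and adjusted p = 0.537 with an estimated correlation. The pharyngeal myosin gene myo-2 was at 3.14, 3.02 and 9.82 CPM in ME against 36, 26 and 130 in the wild type (-3.59 ± 0.78, adjusted p = 0.00739), so the wild-type replicates themselves differed widely. Of the touch receptor genes 5 of 16 fell and 1 rose (6 and 2 adjusted over the list alone). For this list the camera adjusted p was 0.00332, and adjusted p = 0.538 with an estimated correlation. Tubulins fell in 4 of 14 cases (4 adjusted over the list alone, camera adjusted p = 0.00734, and adjusted p = 0.382 with an estimated correlation), while the list's median was 0.01, and -0.02 with DESeq2 size factors. Among them ben-1 fell by 0.72 on the log2 scale (adjusted p = 6.01e-05). FMRFamide-like peptide genes rose in 12 of 30 cases (13 adjusted over the list alone), with a median of 0.28. Camera returned an adjusted p of 0.0219, and adjusted p = 0.682 with an estimated correlation, led by flp-9 at 0.52 ± 0.08 (adjusted p = 0.000664). Pan-neuronal genes fell in 7 of 36 cases (6 adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.0422, and adjusted p = 0.774 with an estimated correlation), and unc-18, a vesicle fusion gene, fell by 0.48 (adjusted p = 0.00071).

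Body wall muscle genes split in ME, with 19 of 34 up and 4 down (19 and 4 adjusted over the list alone), and a median of 0.20. The camera adjusted p was 0.0441, and adjusted p = 0.774 with an estimated correlation. The giant sarcomere genes ttn-1 and unc-22 fell by 1.01 and 1.00 on the log2 scale (adjusted p = 8.60e-05 and 8.27e-05), whereas the myosin light chain gene mlc-3 rose by 0.62. Nuclear oxidative phosphorylation genes rose in 14 of 41 cases and fell in 2 (camera adjusted p = 0.00831, and adjusted p = 0.774 with an estimated correlation), major sperm proteins had a median of 0.80 with 1 of 31 up (0.000207, and adjusted p = 0.774 with an estimated correlation; a median of 0.46 with 25 called under the axis covariate, and 1.19 with 31 called with replicates 1 and 2 alone), and glutathione and UDP-glucuronosyl transferases fell in 32 of 94 cases and rose in 4 (0.000366, and adjusted p = 0.537 with an estimated correlation). Adjusted over the list alone these lists had 18, 0 and 6 members up and 2, 0 and 32 down. The camera call for muscle was lost without wild-type replicate 1 (0.0892) or 2 (0.101) and without ME replicate 2 (0.137) or 3 (0.361), that for pan-neuronal genes without wild-type replicate 1 (0.0845) or 2 (0.107), that for FMRFamide-like peptides without wild-type replicate 3 (0.0582) and that for oxidative phosphorylation without wild-type replicate 2 (0.0511). Reference genes were not level in ME, since 2 of 8 rose and 4 fell (median -0.05, camera adjusted p = 0.907).

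**Figure D4:**
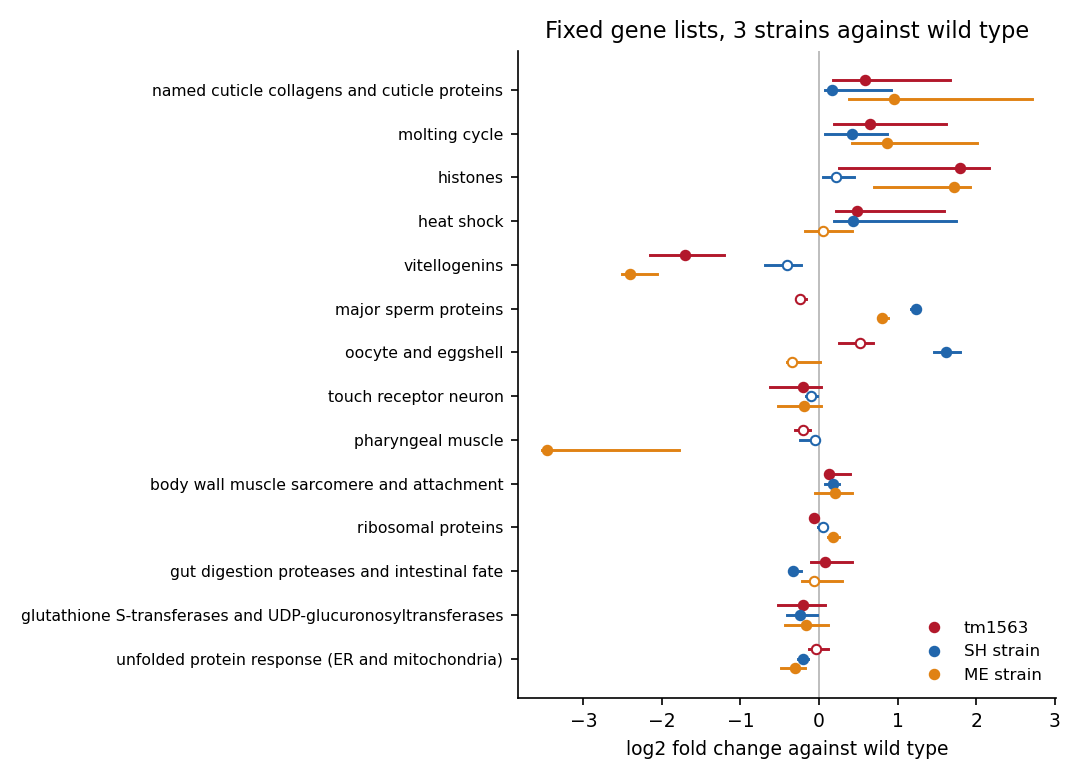
Median log2 fold change (points) and quartiles (bars) of the members of 14 gene lists for tm1563, SH and ME against the wild type. Filled points passed camera at an adjusted p under 0.05, with histones at 1.79 in tm1563 and 1.72 in ME, and pharyngeal muscle at -3.46 in ME.

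SH and ME were set against each other to see what follows the choice of isoform, and 3813 genes differed, 1637 higher in SH and 2176 higher in ME. The balance turned over with DESeq2 size factors, with 1934 higher in SH and 1775 higher in ME, and by a log2 change of 1 or more, with 601 and 528. The touch receptor tubulins were higher in SH, mec-12 by 0.88 (adjusted p = 0.000104) and mec-7 by 0.85 (adjusted p = 0.000125), as were mec-17 by 0.56 (adjusted p = 0.000513) and ben-1 by 0.72 (adjusted p = 0.000125). The giant sarcomere genes unc-22 and ttn-1 were higher in SH by 1.42 ± 0.11 and 1.28, but the body wall muscle list had a median of -0.11, with 8 of 34 higher and 7 lower (8 and 11 adjusted over the list alone, camera adjusted p = 0.553). Named cuticle, histone and gut protease genes were lower in SH, with noah-1 at -1.67 and cpr-1 at -2.56 ± 0.19 (79.5 against 469 CPM, adjusted p = 5.29e-05). The count was 2329 without SH replicate 1, 2373 without ME replicate 1 and 2216 without ME replicate 2.

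Named cuticle genes were lower in SH than in ME in 19 of 26 cases and higher in 2 (median -0.92, camera adjusted p = 7.54e-12, and adjusted p = 0.382 with an estimated correlation), and histones lower in 20 of 28 (median -1.38, camera adjusted p = 1.46e-11, and adjusted p = 0.377 with an estimated correlation). Oocyte genes were higher in 13 of 23 cases (median 1.96, camera adjusted p = 3.00e-08, and adjusted p = 0.553 with an estimated correlation; median 1.19 with the axis covariate), heat shock genes higher in 8 of 14 and lower in 1 (median 0.60, camera adjusted p = 8.08e-07, and adjusted p = 0.337 with an estimated correlation), and pharyngeal muscle genes higher in 6 of 8 (median 3.30, camera adjusted p = 5.65e-05, and adjusted p = 0.486 with an estimated correlation). Gut genes were lower in 10 of 19 cases and higher in 1 (camera adjusted p = 2.91e-08, and adjusted p = 0.382 with an estimated correlation), ribosomal proteins lower in 24 of 77 (4.55e-05, and adjusted p = 0.774 with an estimated correlation), and cytochrome P450 genes lower in 22 of 65 and higher in 4 (0.000332, and adjusted p = 0.340 with an estimated correlation). The col collagens went against the named cuticle genes, with 38 of 121 higher in SH and 21 lower (55 and 27 adjusted over the list alone), a median of 0.37 (0.60 with replicates 1 and 2 alone) and a camera adjusted p of 0.000164, and adjusted p = 0.602 with an estimated correlation. Touch receptor genes were higher in 4 of 16 cases and lower in 1 (camera adjusted p = 0.014, and adjusted p = 0.602 with an estimated correlation). Adjusted over the list alone, 19 cuticle genes, 23 histones, 13 gut genes, 26 ribosomal proteins and 27 cytochrome P450 genes were lower, and 21 oocyte, 10 heat shock, 6 pharyngeal muscle and 5 touch receptor genes higher. Splicing regulators had a median of -0.01, which turned to 0.03 with DESeq2 size factors. The lipid and defence genes lipl-3 (-2.56 ± 0.35, adjusted p = 0.000687) and clec-60 (-2.93 ± 0.31, adjusted p = 0.000249) were among those lowest in SH relative to ME.

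The tm1563 mutant was then compared with the edited strains, to see how the mutant differs from strains with 1 isoform. Against SH, 4509 genes differed, 2531 higher in tm1563 and 1978 lower, and against ME 4028, 2226 higher and 1802 lower. By a log2 change of 1 or more the balance was the other way, with 288 higher and 1097 lower against SH and 266 and 429 against ME. DESeq2 size factors gave 2132 higher and 2174 lower against SH. Touch receptor genes were lower in tm1563 than in SH in 4 of 16 cases and higher in 1 (camera adjusted p = 6.12e-07, and adjusted p = 0.370 with an estimated correlation). Against ME, 4 were lower and 2 higher (camera adjusted p = 0.00597, and adjusted p = 0.553 with an estimated correlation, with 0.066 without tm1563 replicate 3), with mec-7 at -1.44 (adjusted p = 2.25e-06) and mec-12 at -0.78 (adjusted p = 0.000165) relative to ME. Gut protease genes were higher in tm1563 than in SH in 14 of 19 cases (median 0.41, camera adjusted p = 2.49e-13, and adjusted p = 0.327 with an estimated correlation), and splicing regulators in 17 of 42 (median 0.17, camera adjusted p = 0.000723, and adjusted p = 0.486 with an estimated correlation). Ribosomal proteins were lower in tm1563 than in ME in 53 of 77 cases (median -0.24, camera adjusted p = 2.66e-13, and adjusted p = 0.553 with an estimated correlation), while the unfolded protein response was higher in 16 of 23 and lower in 1 (median 0.34, camera adjusted p = 3.89e-07, and adjusted p = 0.429 with an estimated correlation). Adjusted over the list alone the counts were 14 gut genes and 18 splicing regulators higher against SH, and 61 ribosomal proteins lower and 17 unfolded protein response genes higher against ME. With the axis covariate the gut genes had a median of 0.22 against SH with 7 called, and splicing regulators 0.08 with 2 called.

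Against SH, major sperm proteins were lower in tm1563 in 27 of 31 cases (median -1.49, camera adjusted p = 1.05e-13, and adjusted p = 0.488 with an estimated correlation), col collagens lower in 57 of 121 and higher in 4 (median -0.55, camera adjusted p = 8.04e-10, and adjusted p = 0.435 with an estimated correlation), and pals genes higher in 11 of 25 (median 0.74, camera adjusted p = 0.000101, and adjusted p = 0.329 with an estimated correlation). The counts adjusted over the list alone were 29, 65 and 15. With the axis covariate these lists had medians of -0.47, -0.46 and 0.41 with 10, 3 and 4 members called. With the replicate number as a block the camera adjusted p against SH went from 0.0592 to 0.00874 for germline genes, from 0.0576 to 0.0462 for pathogen response genes and from 0.0193 to 0.0558 for the mitochondrial genome. With an estimated correlation and no block these were adjusted p = 0.833, 0.602 and 0.752. The call of the mitochondrial genome was also lost without SH replicate 2 (0.0564) or 3 (0.0502) or tm1563 replicate 3 (0.149). The count against SH was 2254, 2176 and 2321 without tm1563 replicate 1, tm1563 replicate 2 and SH replicate 3, and 782 with the axis covariate. The count against ME was 2408, 2201 and 2586 without tm1563 replicate 1, tm1563 replicate 2 and ME replicate 2, and 6262 with replicates 1 and 2 alone. Among single genes, Y68A4A.13 was higher in tm1563 than in SH by 4.59 ± 0.22 (17.7 against 0.728 CPM, adjusted p = 1.94e-07), and cest-1.1, a carboxylesterase gene, was lower than in ME by 3.06 (3.68 against 30.7 CPM, adjusted p = 8.86e-06).

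Some genes changed in all 3 mutant strains. In each of them 115 genes rose and 204 fell, where independent lists of these lengths would share 9.2 and 11.4. The gene far-3 fell by 2.59, 1.47 and 1.73 on the log2 scale in tm1563, SH and ME, and hmit-1.1, which encodes a proton-linked myo-inositol transporter, by 0.77, 0.77 and 0.98. Between pairs of strains, tm1563 and ME shared 789 genes that rose and 587 that fell (219.8 and 168.7 for independent lists), SH and ME 265 and 612 (97.2 and 164.1), and tm1563 and SH 157 and 263 (59.6 and 71.5). Simulated unchanged groups shared 0 calls, but groups without changes have few calls to share. The simulation therefore gives no expected value for these overlaps, and part of the excess may come from the shared wild-type libraries. Fold changes correlated across genes with Pearson r of 0.51 for tm1563 and ME, 0.35 for SH and ME and 0.15 for tm1563 and SH (Spearman 0.43, 0.49 and 0.16). Unchanged groups against the same wild-type libraries gave 0.50, 0.50 and 0.49 (Spearman 0.45, 0.45 and 0.44). The covariances were 0.188, 0.145 and 0.042 against a simulated 0.046, which left 0.142, 0.099 and -0.003. The simulation drew each library independently, and same-numbered replicates of some strains deviated together. Computed on log2 CPM, chosen after the simulation was seen, the noise of the replicates gave covariances of 0.021, 0.034 and 0.04 with that pairing, where independent replicates gave 0.046. On log2 CPM the covariances of the fold changes were 0.149, 0.139 and 0.025. The values left of these were 0.128, 0.105 and -0.014 with the pairing, and 0.102, 0.093 and -0.021 without it.

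Muscleblind proteins act on alternative splicing, and the authors' deposited lists of events were compared next. In tm1563 the authors' deposited table listed 389 events in 279 genes, 8.4% of 4627 tested, and 265 were cassette exons. SH had 322 events in 262 genes (7.0% of 4590) and ME 258 in 205 genes (5.5% of 4719) in the authors' deposited tables. In 220 of the 265 cassette exons of tm1563 the length was a multiple of 3. The replicates of mutant and wild type did not overlap for 265 of the 389 events (68.1%) in tm1563, 186 (57.8%) in SH and 109 (42.2%) in ME, in events that had been listed from those same replicates. Of the cassette exons tested, a larger share was listed in tm1563 (7.9%) than in SH (5.7%, Fisher's exact test, adjusted p = 0.00174 over 15 tests) or ME (4.9%, adjusted p = 1.30e-05). Of the alternative 3' splice sites tested, a larger share was listed in SH (15.2%) than in tm1563 (6.7%, adjusted p = 0.000217 by Fisher's exact test) or ME (7.0%, adjusted p = 0.000269). In SH 57 of those 73 alternative 3' splice site events were higher than in the wild type and 16 lower (exact binomial test, p = 1.53e-06). These tests count events as independent, although strains share the wild-type libraries and some genes hold several events. They do not measure the spread between replicates. SH libraries also scored high on the within-strain axis (26, 21.3 and 55, against -30.5, -34.1 and 14.6 in the wild type). The splicing events were not adjusted for that axis, so its part in the SH events was not tested.

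The following events were chosen after their values were seen, as those with at least 20 informative reads in each replicate, because many of the largest differences named by rule rested on replicates with 0 reads. In the authors' deposited table for tm1563, the 51-base exon of the touch receptor factor gene mec-3 (IV:10461243 to 10461293) went from 1.0 in each wild-type replicate to 0, 0.046 and 0.11, and it was listed for neither SH nor ME. The same table gave differences of -0.884 for an exon of the intermediate filament gene ifb-2 (II:5752817 to 5752867), -0.711 for an 18-base exon of the Mediator gene rgr-1 (III:9396931 to 9396948), and 0.626 for an exon of the dynactin gene dnc-1 (IV:10932237 to 10932320). It also gave 0.631 for the nidogen gene nid-1 (V:12914221 to 12914391) and 0.747 for a 9-base alternative 5' splice site of unc-104 (II:7008395 to 7008403). In SH the authors' deposited table gave smaller differences for the same exons, -0.301 for ifb-2, -0.523 for rgr-1, 0.404 for dnc-1 and 0.337 for nid-1. The exon of unc-43, which encodes the calcium and calmodulin-dependent kinase II (IV:10327602 to 10327715), differed by 0.433 in tm1563 and 0.277 in SH in the authors' deposited tables, and an exon of the RNA-binding protein gene etr-1 (II:168175 to 168393) by 0.494, 0.412 and, in ME, 0.179. In ME the authors' deposited table gave -0.399 for an exon of the active zone gene unc-10 (X:7273830 to 7274144) and -0.388 for one of the sodium leak channel gene unc-80 (V:20889840 to 20889971), which differed by 0.232 and 0.276 in tm1563.

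Of the 389 events of tm1563, 156 were also listed for SH, where independent lists would share 27.3, and 150 of them had the same direction in the authors' deposited tables. The difference was smaller in SH for 123 of the 156. Both lists use the same wild-type libraries, and no value for unchanged groups could be simulated from lists of called events. In an exon of F49E2.5 (X:9555416 to 9555577), for example, the wild-type replicates were at 0.154, 1.0 and 1.0 in the authors' deposited tables, and the event was listed in the same direction for all 3 mutants. The strains tm1563 and ME shared 100 events (22.4 for independent lists), 81 in the same direction, and SH and ME shared 74 (19.1), 57 in the same direction and 17 opposite. Listed for all 3 strains were 41 events, and 174 were listed for tm1563 alone. More tm1563 events were shared with SH alone (115) than with ME alone (59, exact McNemar test, p = 2.63e-05), though the SH list is longer. Opposite differences in SH and ME in the authors' deposited tables included an exon of the potassium channel gene twk-2 (-0.197 and 0.37, II:4447055 to 4447267) and one of skpo-3 (0.221 and -0.075, II:7246824 to 7247246). Part of the excess may come from the wild-type libraries that the lists share.

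**Figure D5:**
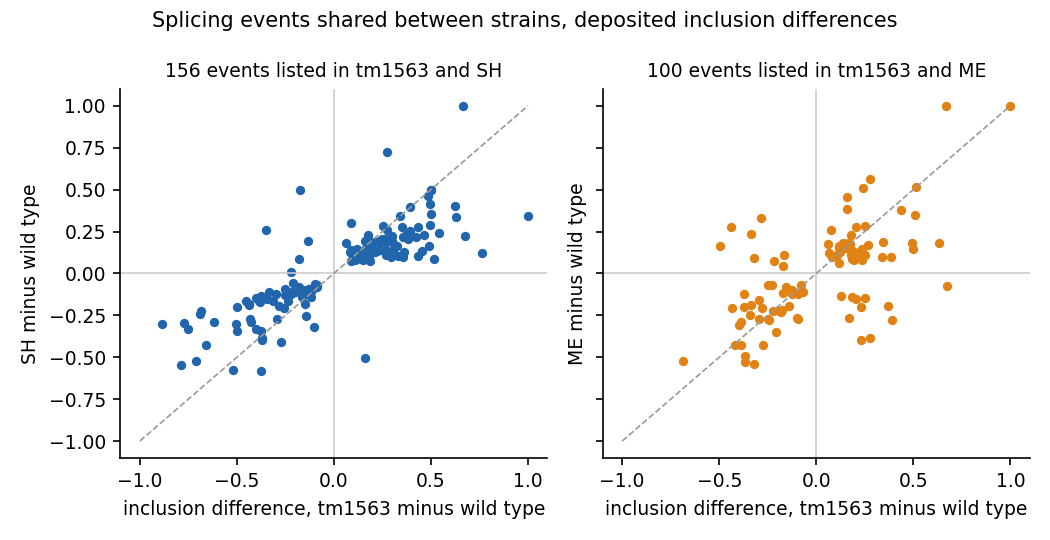
Difference in inclusion from the wild type of splicing events listed for tm1563 and also for SH (156 events) or ME (100 events), from the authors' deposited tables, with a dashed line where both differences are equal. For SH 150 of the 156 events lie in the quadrants of the same direction, and for ME 81 of the 100.

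Genes with a listed event were compared with the gene lists. Of 36 pan-neuronal genes, 8 had a listed event in tm1563 (slo-1, unc-10, unc-104, unc-11, unc-13, unc-16, unc-31 and unc-36; Fisher's exact test, odds ratio 16.3, adjusted p = 1.22e-05), 4 in SH (adjusted p = 0.0418) and 4 in ME (adjusted p = 0.0245). Of 34 body wall muscle genes, 7 had one in ME (deb-1, dys-1, lev-11, ttn-1, unc-22, unc-52 and unc-89; odds ratio 20.1, adjusted p = 1.22e-05 by Fisher's exact test), 4 in tm1563 (adjusted p = 0.0418) and 3 in SH (adjusted p = 0.156). Other neuronal and muscle lists did not pass. Acetylcholine and GABA genes had adjusted p = 0.613, 0.595 and 0.0575 in tm1563, SH and ME by Fisher's exact test, and touch receptor genes 0.242, 1 and 1. No FMRFamide-like, neuropeptide-like, tubulin or pharyngeal muscle gene had a listed event in any strain. Molting genes with events were fbn-1, let-653, mlt-11 and nas-37 in both tm1563 and SH (adjusted p = 0.0225 each by Fisher's exact test), and fbn-1, let-653 and mlt-11 in ME (odds ratio 10.4, adjusted p = 0.0517 by Fisher's exact test). The background of these tests was not matched on expression or on the number of exons. It was all 15191 genes tested for expression, among them genes with no event to test. Genes with an event were more often changed in expression than other genes, 69 of 269 in tm1563 (25.7%), 43 of 254 in SH (16.9%) and 87 of 200 in ME (43.5%). Against genes matched on expression the odds ratios pooled over strata were 1.59 in tm1563, 1.54 in SH and 1.85 in ME. A permutation test by random draws within the same strata gave p = 0.00252, 0.0166 and 0.0003.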

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

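In this part the tests of the scaling of the libraries, the camera tests of gene lists and the edgeR tests of single genes were planned. All other tests were chosen only after the results were seen. The axis along which replicates of 1 strain differ was rebuilt without the genes of the fixed lists, those of the mitochondrial genome excepted, after a first version over all genes had been seen, and the touch receptor genes were taken as a pattern to weigh in place of the spp-21 locus after looking at the data.

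Some touch receptor and tubulin genes were lower in tm1563, with a median log2 change of -1.41 over the 6 that fell, mec-7, mec-12, mec-17, ben-1, mec-18 and mec-9. Over the whole lists the medians were -0.20 for 16 touch receptor genes and -0.14 for 14 tubulins, and unc-86 and tbb-6 rose. A lower share of neuronal RNA as a whole is argued against by the pan-neuronal list. Its median was 0.03 over 36 genes, with quartiles of -0.12 and 0.16. That list cannot show a lower share of RNA from the touch receptor neurons alone, which was not tested and stays open. The within-strain axis is argued against as well, since 101% of the median was kept with the axis score as a covariate and 6 of 6 genes stayed past the threshold. The share of the mbl-1 exon included does not by itself order the strains. It was 0.716, 0.688 and 0.713 in tm1563 and 1.0 in ME in the authors' deposited tables. Yet 5 of the 6 genes were lower in tm1563 than in ME (mec-7 by 1.44, adjusted p = 2.25e-06). The function left in tm1563 is unknown, so this comparison cannot decide whether the choice of exon affects these genes. Among what stays open is another change of mbl-1 in tm1563, which was not tested. In the authors' deposited table the 51-base exon of mec-3 went from 1.0 in each wild-type replicate to 0, 0.046 and 0.11 in tm1563. It was listed for neither SH nor ME, and a link to the 6 genes was not tested either. Also open is why 4 of the 6 genes were lower in ME than in SH, since each mbl-1 exon state occurs in 1 strain only.

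Stage-linked groups moved in SH and ME. The oocyte genes of SH had a median of 1.62, of which 29.7% was kept with the axis covariate (0.48). The position of the SH libraries on the axis that also separates replicates of 1 strain may thus account for most of that median. The axis score also holds differences between strains, so the covariate cannot tell this position from an effect of the strain on such genes. DESeq2 size factors kept 100.9% of it. They moved the median of all genes in SH only from -0.001 to 0.007, too little to test scaling. The named cuticle genes of ME kept 107.6% of their median with the axis covariate, which argues against position on this axis. Their median loading was at percentile 44.5, so the axis hardly carries these genes. A stage difference off this axis was not tested. DESeq2 size factors kept 96.5% of the cuticle median. They moved the median of all genes in ME only from 0.041 to 0.011, too little to test scaling. Of the 1661 genes called in SH, 85 passed with the covariate, where the median standard error over all genes went from 0.141 to 0.165 and the median absolute log2 change of the called genes from 0.44 to 0.32, so both a smaller effect and a wider error ended the calls. Whether the axis reflects age within L4 or another difference between cultures was not tested, and a biological difference of the strains stays open.

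F56A4.3 and F56A4.9 were raised in both SH and ME. A change of mbl-1 as in tm1563 is argued against by the log2 change of -0.33 of F56A4.3 there. Whether tm1563 removes all mbl-1 function was not tested. No gene that lies over 100 kb away (0 genes) rose by a log2 change of 3 or more in both edited strains. Only these 2 neighbours did, and they raised the question, so the count is weak evidence. A variant at the locus shared by the edited strains may be the source. Of 5 genes tested within 100 kb, only these 2 were called in both strains with the same direction. Y45G12C.16 (V:2530146), within that distance, rose in SH (5.02 ± 1.13, adjusted p = 0.0275) and had a log2 change of -0.16 in ME. The labels do not describe the strains' background, so a shared variant stays a hypothesis.

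The median of the col collagens differed by -0.55 between tm1563 and SH (camera adjusted p = 8.04e-10, and 0.435 with an estimated correlation), since it was -0.36 in tm1563 and 0.21 in SH. The pals genes differed by 0.74 between tm1563 and SH (camera adjusted p = 0.000101, and 0.329 with an estimated correlation), from medians of 0.40 and -0.23. The gut protease and intestinal fate genes differed by 0.41 between tm1563 and SH (camera adjusted p = 2.49e-13, and 0.327 with an estimated correlation), from medians of 0.07 and -0.33. With the axis covariate these 3 differences were -0.46, 0.41 and 0.22, and called members went from 61 to 3, from 11 to 4 and from 14 to 7. The ribosomal proteins differed by -0.24 between tm1563 and ME (camera adjusted p = 2.66e-13, and 0.553 with an estimated correlation), from medians of -0.07 and 0.18. The mbl-1 exon moved in opposite directions, by -0.505 in SH and 0.455 in ME in the authors' deposited tables, a difference that was not tested. The rule for libraries far from the rest of their group does not cover groups of 3, so it was not applied.

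Each comparison of 3 with 3 libraries allows 10 splits, of which 1 is the real one, which is too few for a share under 0.05. The real splits called 2488, 1661, 4758, 3813, 4509 and 4028 genes for tm1563, SH and ME against the wild type, SH against ME, tm1563 against SH and tm1563 against ME, and the highest other splits called 1, 0, 0, 0, 4 and 0. Among the 4 splits that part all 3 pairs of same-numbered libraries, the highest other called 0 for tm1563 against the wild type and 0 against SH.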

How the results depend on the processing

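The added settings (replicates 1 and 2 alone, the axis covariate, the FPKM filter of 1) were chosen only after the results were seen, and the others were planned. No log2 change of a named gene past the threshold changed sign under the planned settings or the FPKM filter of 1. Named genes were not tallied under replicates 1 and 2 alone or the axis covariate. With replicates 1 and 2 alone the pharyngeal muscle median turned from -0.20 to 1.13 in tm1563 and from -0.05 to 1.24 in SH, that of germline genes in tm1563 against ME from 0.13 to -0.64, and that of oocyte genes from -0.34 to 0.46 in ME and from 0.70 to -0.12 in tm1563 against ME. With the axis covariate the medians of germline and oocyte genes in tm1563 against SH turned from -0.67 to 0.25 and from -1.2 to 0.03, that of germline genes in ME from 0.25 to -0.08, and those of major sperm proteins and other sperm genes in SH against ME from 0.44 to -0.09 and from 0.43 to -0.04. Smaller turns were left out. With DESeq2 size factors the share of higher calls went from 42.9% to 52.1% for SH against ME and from 56.1% to 49.5% for tm1563 against SH. In the order tm1563, SH and ME against the wild type, SH against ME, tm1563 against SH and tm1563 against ME, an adjusted p under 0.01 left 1105, 158, 2701, 1563, 1691 and 1801 genes, and an absolute log2 change of 1 or more 493, 358, 1038, 1129, 1385 and 695, fewer because the thresholds are stricter. For SH against the wild type the replicate block called 3393 genes, DESeq2 2969 and the authors' deposited table gave 3080, while replicates 1 and 2 alone called 3547 and the axis covariate 86. The axis covariate left 782 genes for tm1563 against SH, and replicates 1 and 2 alone gave 6262 for tm1563 against ME. Leaving out 1 library gave 1673 to 2036, 176 to 3078, 3579 to 4687, 2216 to 3567, 2176 to 5783 and 2201 to 5305 genes in the same order. The cause was not tested. Lists called numbered 13, 17, 15, 19, 16 and 17, ran over 14 to 16, 17 to 20, 12 to 17, 17 to 21, 16 to 17 and 15 to 19 with 1 library left out, and were 0 in all 6 comparisons with an estimated correlation. The replicate block gave 2613, 5214, 4087, 5354 and 4665 genes for the comparisons other than SH against the wild type, and where numbers pair the libraries it changed no other list call than those given in the report. Correlations of fold changes over genes called in either comparison were 0.334 for tm1563 and SH and 0.623 for tm1563 and ME, and over genes with FPKM of 5 or more 0.493 for SH and ME. A difference in inclusion of 0.2 or more left 188, 103 and 101 splicing events in tm1563, SH and ME, replicates that do not overlap 186 in SH and 109 in ME, and 20 reads 149 in ME. With 1 inclusion value left out, 308 to 317, 233 to 249 and 170 to 200 listed events kept their direction and a minimum difference in inclusion. The full lists do not require that minimum, and events were not called again. Events shared with 20 reads numbered 58 for tm1563 and ME and 36 for SH and ME, since fewer events were compared. Among log2 changes of single named genes, 8650 values of the other settings kept their side of the threshold, 229 lost it and 13 gained it. With 1 library left out these were 4085, 710 and 3. Replicates 1 and 2 alone and the axis covariate are not in these tallies. All 6 odds ratios of changed and spliced genes kept their direction and call. Depth limits genes under about 10 reads and events under 20.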

Other observations

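The genes of this part and its added settings were chosen only after the results were seen, while the edgeR tests were planned, and no explanation is offered. T25C12.3 (X:11491095), a neighbour of spp-9 and spp-21, fell in tm1563 from 2519 to 723 CPM (-1.80 ± 0.10, adjusted p = 1.43e-06), beside the rise of both saposin-like genes. In SH and ME its log2 changes were -0.30 (adjusted p = 0.0705) and -0.52 (adjusted p = 0.00222). The decay factor gene smg-6 fell in all 3 mutants, by 0.61, 0.52 and 0.29 on the log2 scale, and tm1563 and SH also had a listed splicing event in it in the authors' deposited tables. The giant sarcomere genes went different ways, with ttn-1 at 1.15, 0.28 and -1.01 and unc-22 at 0.77, 0.41 and -1.0 in tm1563, SH and ME.

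With replicates 1 and 2 alone, the pharyngeal muscle list had medians of 1.13, 1.24 and -3.08 in tm1563, SH and ME. In tm1563 myo-2 was at 73.2, 79.2 and 26.9 CPM and in SH at 67.2, 86.2 and 42.5, against 36, 26 and 130 in the wild type. The genes that kept their call in SH with the axis covariate included hsp-70 (2.43 ± 0.18), hsp-16.2 (2.92), hmit-1.1 (-0.69) and COX3 (0.89).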
